A study of Equus caballus with 14 samples.

How the data were processed

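The series holds 14 deposited array files of horse (Equus caballus) total RNA: 4 chorionic girdle and 4 chorion samples of the same 4 conceptuses, 2 fetus samples of 2 of these conceptuses, 1 resting and 1 mitogen-stimulated lymphocyte sample of 1 mare, and 2 girdle files deposited again under a reanalysis label. The copies held the same processed and median signals at every spot and were left out, so that each girdle sample counted once. Groups and conceptus numbers were taken from the sample titles and source names. Per the labels, RNA integrity numbers were above 9.0, 1 ug of RNA was labelled with Cy3, and RNA of the stimulated cells was pooled from days 1 to 5.

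Per the file headers, spot intensity was extracted with Agilent Feature Extraction 9.5.1.1 for conceptuses 3637, 3959 and 3961 and with 10.5.1.1 on a second scanner model for conceptus 3879 and the lymphocytes, while the submitters' processing notes name version 9.1. The processed intensity is a background-subtracted, detrended signal on a linear scale in which dim spots hold a surrogate value, per the file headers. The authors' deposited comparison tables give raw intensity, log2 values normalized by the authors, fold changes as an absolute ratio, and p-values; the ratio is linear with its direction in a separate column. For girdle against chorion, 100% of the authors' p-values lay within 0.0001 of a paired test on the log2 values in the same deposited table. How the authors scaled the arrays is not given in the sources used here. Pair differences in the authors' deposited table differed from those here by a median of 0.12 with the 75th percentile scaling and 0.024 with quantile normalization. The tables' group means and folds served only for comparison.

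Processed signals of the 15057 non-control spots were taken as log2, and the 75th percentile of each array was subtracted. Between 28 and 205 spots per array carried an outlier flag and were left out; saturated spots, up to 549 per array, were kept. The 150 probes spotted 6 times were averaged and 14157 probes had 1 spot, which gave 14307 probes. The 75th percentile of the signal ranged from 940 for the chorion array of conceptus 3637 to 8255 for the fetus array of conceptus 3959, so dim transcripts were measured less well in conceptus 3637. Arrays carry no count depth, and their number limits the precision.

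The probes are named by transcript accessions, 13773 predicted RefSeq, 210 other RefSeq and 324 of other kinds. The gene name column repeats the accession and 0 probes have a description, so the files do not pair probes with genes, and no reference table was used here. The 30 gene lists fixed before the data were examined and the genes fixed by name therefore could not be matched to probes, and the list tests (limma camera) were not run. The rule for named probes was fixed before the data were examined and asked for a gene symbol; it was applied to probes instead, and stopped at 2 per direction. For girdle against chorion and against fetus it takes the largest mean log2 differences among probes past the threshold, changed the same way in every conceptus and well above background on every array of both groups. For lymphocytes it takes the largest changes among probes well above background on both arrays. Probe sequences are those of the files; no genome position is given because the files mark every probe as unmapped.

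Girdle was compared with chorion on 8 arrays and with fetus on 10 arrays (girdle, chorion and fetus together, so that chorion adds to the estimate of the spread), using limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the package data.table (version 1.17.8) to read the files. Conceptus was a fixed block, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. A probe entered if it was well above background on every array of at least 1 of the 2 groups. The conceptuses are separate animals, and each gave both tissues, as the series design states. Deviations of girdle and chorion from their group means correlated across probes at 0.39 to 0.73 within a conceptus and at no more than 0.13 between conceptuses. The low values between conceptuses are partly built in, because the deviations of a group cancel out across its arrays. Each conceptus lay on 1 slide scanned on its own, so the conceptus block also takes up slide and scan, and per-conceptus differences are within-slide values. The slide of conceptus 3879 also held the lymphocytes.

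Where a probe was well above background on all arrays of a group and none of the other, its fold was given as a bound: the mean of the bright group against the mean, over the dim arrays, of the higher of the array's lowest signal well above background and the probe's own. For girdle against fetus the bound used the girdle arrays of the 2 conceptuses with a fetus array. For the lymphocytes, a list's median change was set among the medians of 10000 random lists of the same size matched on signal level in 20 bins, or in 10 level bins and 5 bins of probe GC content, as a description of these arrays. The covariance of the 2 girdle comparisons was set against 20 simulations of unchanged groups, in which almost no probe was called, so that they say nothing of the overlap of calls.

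The fits were tested on simulated data with 200 changed probes. For girdle against chorion, with 10610 probes, 48% of changes of 2-fold and 95% of changes of 4-fold were recovered, with 9 unchanged probes called. For girdle against fetus, with 12590 probes, these shares were 9% and 75%, with 3 unchanged probes called. In the data 50.2% and 55.6% of tested probes were called, which makes the adjusted threshold less strict than with 200 changed probes. The shares recovered therefore hold for the simulated setting and do not give the power of the fits to the data. Alternatives were quantile normalization, normexp background correction (offset 50) with either scaling, no filter and a stricter filter on dim probes, no block, slide as the block, an intensity trend in eBayes, other sets of arrays, outlier spots kept, each conceptus left out, and a paired test per probe at an unadjusted p under 0.05 and after adjustment. Normexp used the median spot signal in place of the mean, which 8 of the 12 arrays have. Removal of the trend on probe GC content, exclusion of saturated probes and a looser filter for the lymphocytes were added after seeing the data. Figures were drawn with matplotlib 3.10.9.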

Results

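Transcript levels were measured in horse conceptus tissues of days 33 to 35 of gestation and in blood lymphocytes of a mare, on 1-colour Agilent arrays with 14307 distinct 60-base probes. The chorionic girdle is the band of invasive trophoblast from which the endometrial cups of the mare arise, and the chorion beside it is non-invasive trophoblast. Chorionic girdle and chorion were each measured in 4 conceptuses, named 3637 (day 33), 3879 (day 34), 3959 (day 34) and 3961 (day 35). Tissue of the fetus itself was measured in conceptuses 3959 and 3961. Lymphocytes of mare 3729 were measured at rest and after stimulation with pokeweed mitogen, a plant lectin that drives lymphocytes to divide, with 1 array per condition and RNA of days 1 to 5 of culture pooled for the stimulated sample. The girdle arrays of conceptuses 3959 and 3961 were each deposited a second time with identical signals at every spot, and each was counted once, which left 12 arrays. Between 72.7% and 92.7% of the probes were well above background on an array. Probes spotted 6 times on each array varied by a median coefficient of variation of 3.21% to 9.46% within an array, the highest value being that of the girdle array of conceptus 3961. The number of arrays per group limits the precision of every comparison.

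The 4 tissues separated on the first 3 principal components of the 12 arrays. The first component held 36.4% of the variance and set the lymphocytes apart from the conceptus tissues, the second held 29.1% and set the fetus apart, and the third held 14.5% and parted girdle from chorion. Across probes, girdle arrays correlated with one another at r = 0.952 to 0.966 and with chorion arrays at 0.892 to 0.933. Fetus arrays correlated with girdle arrays at 0.775 to 0.821 and with chorion arrays at 0.801 to 0.833. Probes are not independent replicates, so these correlations describe the arrays and carry no p.

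**Figure D1:**
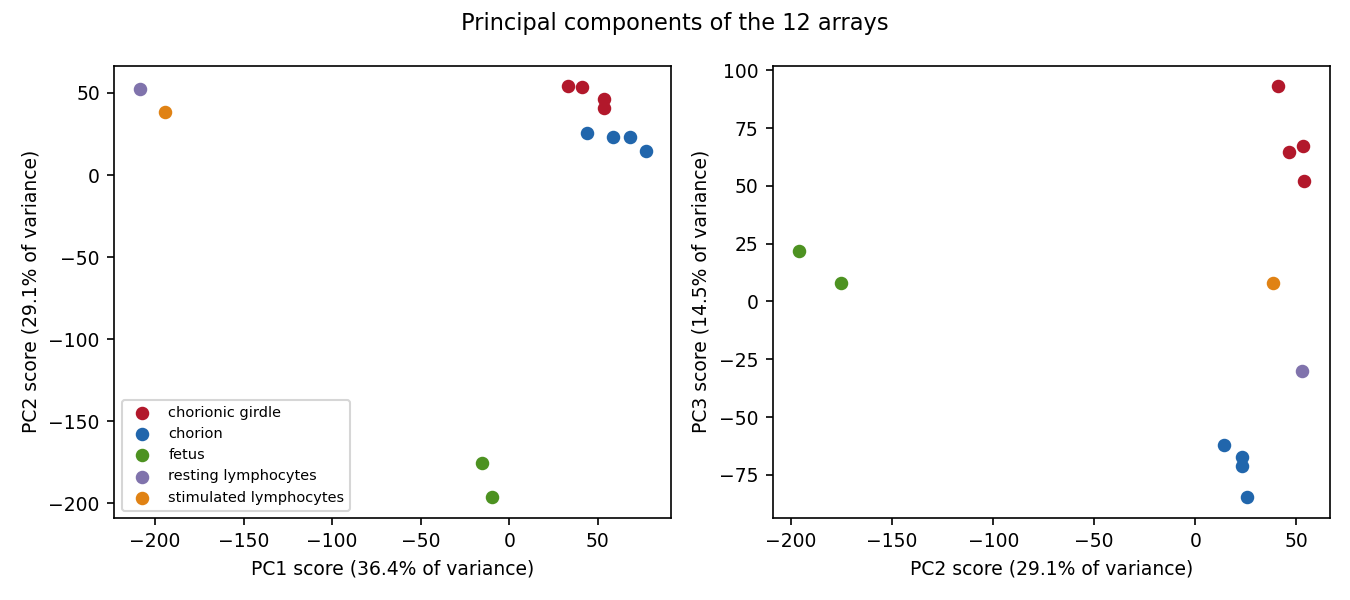
Scores of the 12 arrays on the first 3 principal components (arbitrary units, axis labels give the percent of variance), one point per array coloured by tissue. On the third component the 4 girdle arrays have positive scores of up to 93.1 and the 4 chorion arrays negative ones down to -84.7.

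Chorionic girdle was first compared with chorion of the same conceptus, to ask which transcripts differ between these tissues. The mix of cell types in each tissue was not measured. Of 10602 probes tested, 2489 were higher and 2835 lower in girdle. A difference of at least 2-fold was reached by 1095 probes that were higher and 1829 that were lower, one of at least 4-fold by 426 and 798, and one of at least 16-fold by 92 and 115. All 4 conceptuses changed the same way for 2441 of the 2489 higher probes and for 2767 of the 2835 lower ones. Agreement among conceptuses is partly built in, because the calls rest on the same differences. Calls rested on limma with conceptus as a block and a Benjamini-Hochberg adjusted p under 0.05. The files name each probe by a transcript accession and do not pair it with a gene name, so no gene, pathway or cell type is named here, and 2 probes per direction stand for each comparison.

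Probe XM_001501422.1 (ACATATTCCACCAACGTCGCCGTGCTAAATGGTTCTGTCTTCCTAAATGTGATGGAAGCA) showed the largest estimated increase in girdle among probes well above background on all 8 arrays. Its log2 level, relative to the 75th percentile of the array, was 4.18 ± 1.20 (SD, n = 4) in girdle and -4.73 ± 0.76 (SD, n = 4) in chorion. The estimated difference was 8.92 ± 0.37 (SE; limma adjusted p = 0.000355), and the values of the 4 conceptuses lay between 8.24 and 10.32. In fetus the level of this probe was -5.10 ± 0.57 (SD, n = 2), near that of chorion. Probe XM_001503726.1 (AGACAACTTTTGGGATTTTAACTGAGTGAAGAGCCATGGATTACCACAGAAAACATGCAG) stood at 4.80 ± 1.13 (SD, n = 4) in girdle and -3.32 ± 0.76 (SD, n = 4) in chorion, an estimated difference of 8.12 ± 0.26 (SE; limma adjusted p = 0.000225). It was not well above background on either fetus array, and in conceptuses 3959 and 3961 girdle was at least 4436-fold higher than fetus (limma adjusted p of the fitted difference = 1.03e-05). Both probes saturated the scanner in girdle, XM_001501422.1 on 2 arrays and XM_001503726.1 on 3. Saturation caps the signal, so both values understate the difference at this scaling, no fold is given, and the order of the probes was not measurable. Over the alternatives the difference was 8.01 to 9.14 for XM_001501422.1 and 7.53 to 8.29 for XM_001503726.1.

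Probe XM_001504475.1 (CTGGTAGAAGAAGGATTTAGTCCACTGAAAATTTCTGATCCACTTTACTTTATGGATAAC) and probe XM_001499988.1 (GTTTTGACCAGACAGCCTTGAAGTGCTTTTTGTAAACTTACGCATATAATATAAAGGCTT) showed the largest estimated decreases by the same criteria. XM_001504475.1 was at 3.63 ± 0.15 (SD, n = 4) in chorion and -2.79 ± 1.91 (SD, n = 4) in girdle. The estimated difference was -6.42 ± 0.68 (SE; limma adjusted p = 0.00170), which understates the decrease at this scaling because 1 chorion array was saturated. It ranged from -8.74 to -4.95 over the conceptuses. XM_001499988.1 was at 0.14 ± 0.55 (SD, n = 4) in chorion and -6.15 ± 0.31 (SD, n = 4) in girdle, a difference of -6.29 ± 0.33 (SE; limma adjusted p = 0.000456), or 78.1-fold. Without conceptus 3961 the differences were -5.65 for XM_001504475.1 and -6.50 for XM_001499988.1, so the order of these probes is not settled. Over all alternatives they were -6.91 to -5.65 and -6.54 to -4.77. The level of XM_001499988.1 in fetus was -0.91 ± 0.05 (SD, n = 2).

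**Figure D2:**
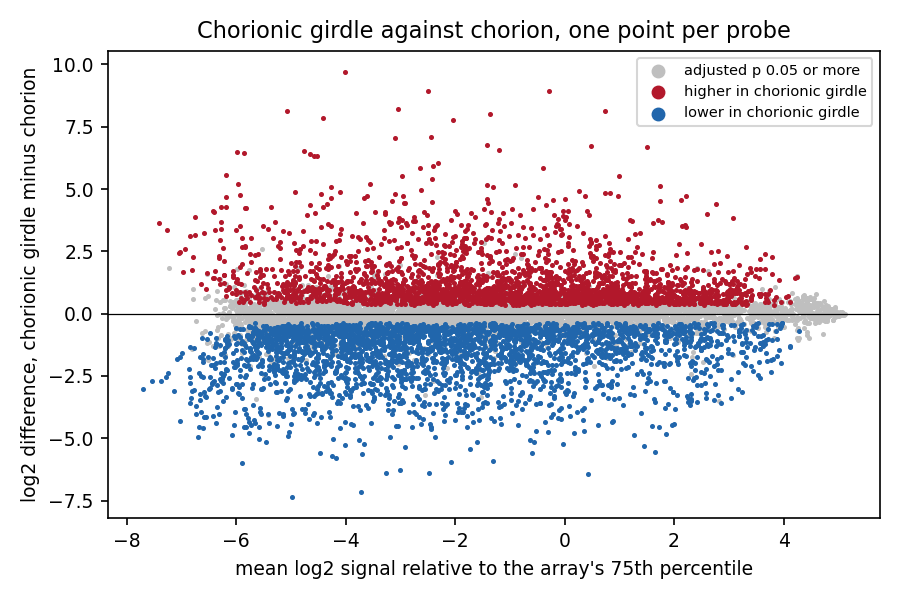
Log2 difference, girdle minus chorion, against the mean log2 level of both tissues relative to the array's 75th percentile, one point per tested probe. Red points are the 2489 probes higher and blue points the 2835 lower in girdle at a limma adjusted p under 0.05.

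**Figure D3:**
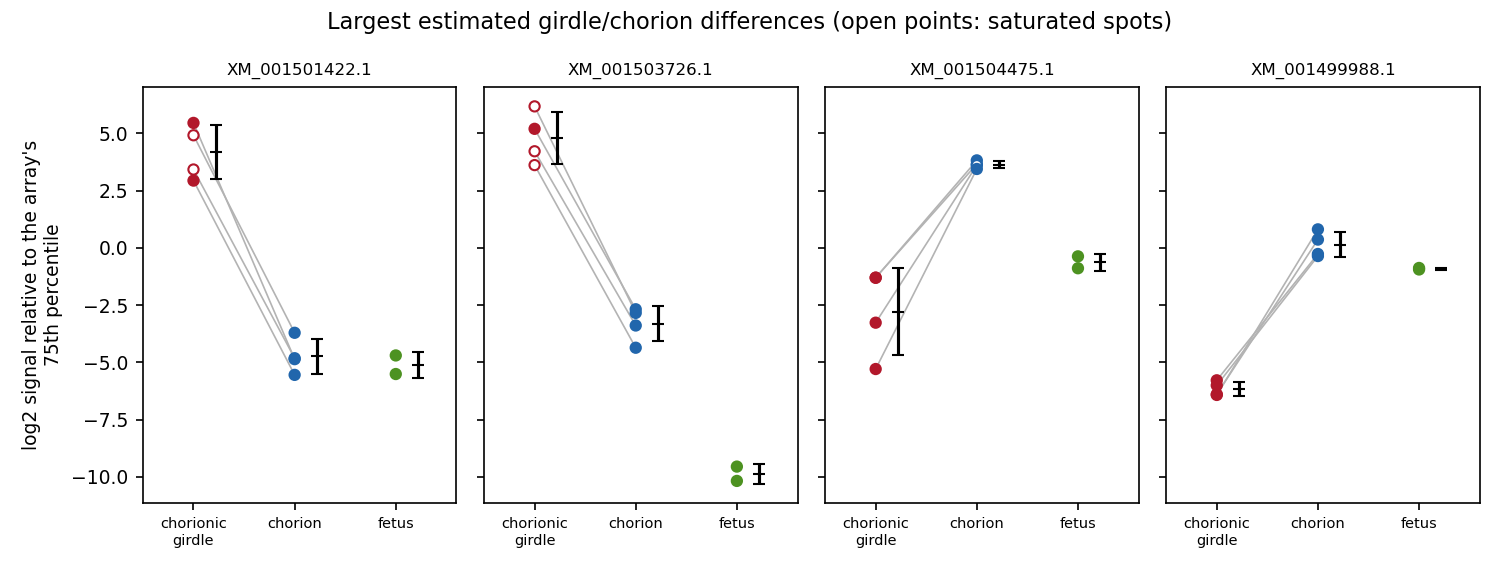
Log2 level relative to the array's 75th percentile, per array, of the 4 probes named for girdle against chorion. These had the largest estimated differences, 2 per direction, among probes well above background on every girdle and chorion array. Open points are saturated spots, and lines join girdle and chorion of the same conceptus. Bars give mean and SD (n = 4 for girdle and chorion, n = 2 for fetus). The girdle and chorion points do not overlap for any of these probes.

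Some transcripts were measured in 1 of the 2 tissues alone. A set of 20 probes was well above background on all 4 girdle arrays and on no chorion array, with bounds of up to at least 236-fold and a median bound of at least 8.35-fold. In the other direction, 34 probes were well above background on all 4 chorion arrays and on no girdle array, with a median bound of at least 5.91-fold and the highest at 53.6-fold. All 20 and all 34 were past the limma threshold.

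Of the 1095 probes at least 2-fold higher in girdle, 97.2% were well above background on both fetus arrays and 88.2% on the resting lymphocyte array. Of the 1829 at least 2-fold lower in girdle these shares were 97.0% and 82.4%, and of the 5278 probes not called they were 99.5% and 96.7%. The median level of the girdle-higher set was -0.58 in girdle, -2.77 in chorion and -1.78 in fetus, and that of the girdle-lower set was -3.62, -1.43 and -2.04.

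The count of calls without the conceptus block was 2648, with 1050 higher and 1598 lower in girdle, so the block moved it by over 1.5 times. Scaling moved the balance of directions: under quantile normalization, which shifted the median difference of all tested probes from -0.03 to 0.08, 2984 probes were higher and 2409 lower. At least 2-fold differences still numbered 1312 higher and 1542 lower, at least 4-fold ones 466 and 694, and at least 16-fold ones 99 and 96. At least 16-fold differences fell to 41 higher and 36 lower under normexp with the 75th percentile shift, and to 49 and 34 under normexp with quantile normalization. The authors' deposited table for this comparison lists 3641 probes, 2142 up and 1499 down in girdle, with a highest corrected p of 0.05. Of its 3507 probes tested here, 3247 were called in the same direction and 0 in the opposite one. Of the 5324 probes called here, 2077 are absent from that list.

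Chorionic girdle was next compared with fetus, to ask which transcripts differ between girdle tissue and the embryo proper. Of 12587 probes tested, 3433 were higher and 3566 lower in girdle than in fetus. At least 4-fold differences were reached by 936 probes that were higher and 1894 that were lower, and at least 16-fold ones by 325 and 803. Both conceptuses changed the same way for 3416 of the higher and 3547 of the lower probes, which is again partly built into the calls.

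Probe XM_001488513.1 (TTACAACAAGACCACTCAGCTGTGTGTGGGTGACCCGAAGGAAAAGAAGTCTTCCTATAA) and probe XM_001488406.1 (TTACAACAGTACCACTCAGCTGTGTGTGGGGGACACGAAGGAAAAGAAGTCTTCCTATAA) had the largest estimated excess in girdle among probes measured in both tissues. XM_001488513.1 stood at 3.94 ± 0.62 (SD, n = 4) in girdle and -7.38 ± 0.88 (SD, n = 2) in fetus, and the fitted difference was 11.06 ± 0.25 (SE; limma adjusted p = 7.65e-06). XM_001488406.1 differed by an estimated 10.93 ± 0.32 (SE; limma adjusted p = 9.08e-06). XM_001488513.1 was saturated on 1 girdle and 2 chorion arrays and XM_001488406.1 on 2 of each, so both values understate the difference at this scaling and the order of the probes was not measurable. Over the alternatives the differences were 9.39 to 11.65 and 9.60 to 11.69. Without chorion in the estimate of the spread (2 girdle and 2 fetus arrays alone), each probe had a limma adjusted p of 0.00103. These 2 probes share 56 of their 60 bases, so each may have bound the transcript of the other, and their signals count as 1 observation. No difference between girdle and chorion is given for them, because saturation on both sides would hide one. Their levels in chorion were 4.19 ± 0.72 (SD, n = 4) for XM_001488513.1 and 4.50 ± 0.86 (SD, n = 4) for XM_001488406.1. In resting lymphocytes, where neither probe was saturated, the levels were 5.17 and 5.64. Saturation caps the chorion means, so these values cannot show whether lymphocytes had more. The unsaturated chorion arrays stood at 5.25 and 5.59 in conceptus 3879, on the slide of the lymphocytes, and at 3.82 and 4.77 in conceptus 3637.

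Probe XM_001503104.1 (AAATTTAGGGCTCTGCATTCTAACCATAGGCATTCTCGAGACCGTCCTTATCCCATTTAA) was at 2.83 ± 0.12 (SD, n = 2) in fetus and -5.61 ± 0.72 (SD, n = 4) in girdle, a fitted difference of -8.90 ± 0.22 (SE; limma adjusted p = 7.65e-06), or 477-fold. Probe XM_001504989.1 (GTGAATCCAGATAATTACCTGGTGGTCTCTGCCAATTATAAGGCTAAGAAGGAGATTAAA) was at 3.22 ± 0.26 (SD, n = 2) in fetus and -5.52 ± 0.53 (SD, n = 4) in girdle, a fitted difference of -8.47 ± 0.21 (SE; limma adjusted p = 7.65e-06). It was saturated on both fetus arrays, so this value understates the decrease at this scaling. Over the alternatives the differences were -9.23 to -7.96 for XM_001503104.1 and -9.76 to -7.66 for XM_001504989.1. With the 2 girdle and 2 fetus arrays alone, each probe had a limma adjusted p of 0.00103. Both were also low in chorion, at -4.68 ± 0.60 (SD, n = 4) for XM_001503104.1 and -4.64 ± 0.33 (SD, n = 4) for XM_001504989.1.

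A set of 463 probes was well above background on both fetus arrays and on no girdle array, of which 422 passed the limma threshold and 257 had a bound of at least 4-fold within conceptuses 3959 and 3961. In girdle alone were 31 probes, each with a bound of at least 4-fold and 20 with one of at least 16-fold. The fetus arrays had 87.9% and 91.4% of all probes well above background and the girdle arrays 72.7% to 88.2%.

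With 2 fetus arrays the count depended on each conceptus: 3560 probes passed without conceptus 3959 and 4112 without conceptus 3961, where the lone fetus array was assumed to vary like the other tissues. Without the conceptus block 4405 passed, and under quantile normalization, which moved the median difference from 0.03 to 0.18, 4511 were higher and 3479 lower. Normexp with the 75th percentile shift gave 4157 higher and 3315 lower. At least 4-fold differences still numbered 1193 higher and 1677 lower under the first and 834 and 1296 under the second. At least 16-fold ones numbered 375 and 711 under the first and 257 and 370 under the second. Normexp with quantile normalization gave 860 higher and 1151 lower of at least 4-fold, and 251 and 349 of at least 16-fold. Probes well above background on all 10 arrays, a filter that leaves out those lowest in girdle, gave 3375 higher and 2337 lower, with 817 and 815 of at least 4-fold. The authors' deposited table lists 3540 probes for this comparison, with 2034 up and 1506 down in girdle. Of its 3395 probes tested here, 2760 were called in the same direction and 2 in the opposite one. The authors' list has a highest p of 0.05 and uses conceptuses 3959 and 3961 alone, whereas calls here use 10 arrays and an adjusted p. Of the 6999 probes called here, 4237 are absent from that list.

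Among 10557 probes tested against both chorion and fetus, 1251 were higher in girdle than in either and 1278 were lower than in either, and 798 moved in opposite directions. At least 2-fold differences against both tissues were seen for 575 higher and 873 lower probes. Independent lists of the same lengths would share 791 and 681. The 2 comparisons use the same girdle arrays. With the girdle arrays split, so that chorion was compared in conceptuses 3637 and 3879 and fetus in 3959 and 3961, 585 higher probes were shared against 287 for independent lists, and 826 lower probes against 339. Girdle tissue remains the common term of both comparisons with the arrays split, so overlap above that of independent lists is partly built in. Across probes, the covariance of the log2 differences was 1.16 with all arrays, 1.06 with the arrays split and 0.033 in simulated unchanged groups that shared the girdle arrays. The correlations were 0.44, 0.39 and 0.38. Because the simulated groups hold no differences, the covariances show only that the shared part exceeds array noise.

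Resting and mitogen-stimulated lymphocytes were compared to ask which transcripts change with stimulation. With 1 array per condition there was no replicate check, so no test was made and the values describe these 2 arrays. Of 11235 probes well above background on both, 1365 were at least 2-fold higher and 1908 at least 2-fold lower after stimulation, and 7962 differed by less. At least 16-fold differences were seen for 53 higher and 118 lower probes. The median log2 change was -0.24 with the 75th percentile scaling and -0.07 under quantile normalization, so these counts sit on a shifted centre. With normexp background correction and quantile normalization together the split was 1239 higher and 1095 lower.

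Probe AF035404.1 (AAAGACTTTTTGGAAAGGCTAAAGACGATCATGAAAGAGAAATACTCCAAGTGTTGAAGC) rose from -6.23 to 2.62 on the log2 scale, or 461-fold. It was not well above background on any girdle, chorion or fetus array. Probe XM_001498910.1 (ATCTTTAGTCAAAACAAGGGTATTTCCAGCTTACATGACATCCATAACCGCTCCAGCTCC) was at -6.21 at rest and 2.64 after stimulation, and these 2 had the largest increases. The rankings of increases and decreases cover only probes well above background on both arrays. Probes measured on 1 array alone had bounds of up to at least 394-fold after stimulation and at least 533-fold at rest. The largest decreases were those of the next 2 probes, whose order turned under normexp with the 75th percentile shift. The first was probe XM_001494398.1 (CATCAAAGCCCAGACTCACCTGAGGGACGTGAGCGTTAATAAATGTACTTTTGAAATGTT), from 5.58 to -5.15, or 1701-fold. Probe XM_001498857.1 (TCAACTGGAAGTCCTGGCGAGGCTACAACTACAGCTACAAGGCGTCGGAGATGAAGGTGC) was at 5.55 at rest and -5.10 after stimulation. Normexp with quantile normalization gave smaller changes, 7.41 for AF035404.1 and -8.84 for XM_001494398.1, in the same directions.

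On the stimulated array alone 1969 probes were well above background, and 49 on the resting array alone. The stimulated array had 92.7% of all probes well above background and the resting array 79.2%. Of the 1964 measured after stimulation alone that had a value, 441 had a bound above 1-fold and 135 one of at least 2-fold. Of the 47 probes with a value that were measured at rest alone, 44 had a bound of at least 4-fold. The authors' deposited table for the lymphocytes covers 14302 probes, and its log2 folds correlated across probes with those here at r = 0.986.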

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

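In 32 groups of 4 arrays (array quality measures and named probes, for girdle and for chorion), no array's gap to its nearest neighbour exceeded 0.829 of the group's range, the limit that chance passes in about 1 of 20 groups.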

How the results depend on the processing

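Without the replicate block by conceptus, 2648 probes passed for girdle against chorion and 4405 for girdle against fetus; 2641 and 4357 of these also passed with the block, each in the same direction, and the cause was not tested. Leaving out 1 conceptus gave 3567 to 4795 probes for girdle against chorion and 3560 to 4112 for girdle against fetus, with fewer arrays in each fit. Under all other alternatives run, the total counts of calls stayed within 1.5 times of those reported: 4002 to 5824 probes for girdle against chorion, 5358 to 7990 for girdle against fetus, and 2334 to 4153 lymphocyte probes changed at least 2-fold. These include 3 alternatives chosen after seeing the data: the GC trend removed (5376 against chorion, 7113 against fetus), probes saturated on any array left out (5184 and 6482), and lymphocyte probes well above background on at least 1 array (3889). Counts by size of difference moved more. Against chorion, at least 16-fold differences fell from 92 higher and 115 lower to 41 and 36 under normexp with the 75th percentile shift, and 47 and 59 with the stricter filter. At least 4-fold decreases fell from 798 to 466 under normexp with quantile normalization. Against fetus, at least 16-fold decreases fell from 803 to 349 under normexp with quantile normalization and 370 with the 75th percentile shift. They fell to 233 with the stricter filter, which leaves out probes lowest in girdle. The paired test per probe gave 5412 probes unadjusted and 4002 after adjustment. Slide as the block repeats the conceptus block by construction, and the stricter lymphocyte filter is the one reported.

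All 8 named conceptus probes kept their direction and their call under every alternative that measured them, but their differences moved, as for XM_001499988.1 from -6.29 to -4.77 and XM_001488513.1 from 11.06 to 9.39 under normexp with quantile normalization. The 4 named lymphocyte probes kept their direction under the 6 alternatives run, with the lowest change of AF035404.1 at 7.41 and that of XM_001494398.1 nearest to 0 at -8.84. Averaging probes of a gene, and the gene list shifts against chorion and against fetus under any setting, were not run, because the files do not pair probes with genes. Signal over background limits dim probes most in conceptus 3637, with 72.7% of probes well above background on each of its arrays.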

Other observations

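The tests reported here of GC content, slide, scaling, dim spots and other splits of the arrays were set before their results were seen; those of day of gestation and of array noise, and the comparison by kind of accession, were chosen afterwards. Of 143 tested probes made from RefSeq transcripts other than predicted ones, 15 were higher and 57 lower in girdle than in chorion and the others were not called. Predicted transcripts gave 2448 higher and 2717 lower of 10276, a balance that turned under quantile normalization (2925 and 2312). Probes of other accessions gave 26 higher and 61 lower of 183. The excess of lower probes among the RefSeq transcripts other than predicted ones held under quantile normalization (19 higher, 49 lower), normexp with quantile normalization (18 and 51) and normexp with the 75th percentile shift (14 and 51). The difference between kinds of accession was not tested.

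Some probes named for 1 comparison also differed in another, and were picked out after their values were seen. Probe XM_001494398.1, named for its fall with stimulation, was well above background on 2 of the 4 girdle arrays. Its levels there were -6.22 in conceptus 3879 and -6.44 in conceptus 3961, against -0.87 and -1.70 in chorion of the same conceptuses. Probe XM_001504475.1, named for its decrease in girdle, was measured in resting and not in stimulated lymphocytes.

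The number of probes differing between girdle and chorion was set against other explanations. With each array's trend on probe GC content removed and the block kept, 5376 probes passed against 5324 without the correction, which argues against GC content as the whole cause. Only 8 splits of the arrays part all 4 conceptus pairs as the real one does, too few for a share under 0.05: 1 of them, the real one, reached 5324 probes with the block and 2648 without it, and the highest other gave 0 in both fits. The other splits keep pairs together, so the share of all 35 set as the bound beforehand is no fair one; the highest of them without the block, with 125, set conceptuses 3637 and 3879 against 3959 and 3961.

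Probes at least 2-fold higher in girdle than chorion tended to rise in stimulated lymphocytes. Their median log2 change with stimulation was 0.39 over 964 probes, against -0.36 over 1496 girdle-lower probes and -0.25 over 5076 probes not called, and 34.3% of them rose at least 2-fold against 11.0% and 9.48%. Probe GC content and signal level do not account for it, since the girdle-higher median lay at percentile 100 of 10000 random lists matched on both, whose medians ranged from -0.32 to -0.06. A shared slide and scanner is argued against, because lists made from each conceptus on another slide still differed by at least 0.36 ± 0.05 (bootstrap SD over probes, in conceptus 3961, where the girdle-higher median was only 0.07), and so is scaling, with a difference of 0.71 ± 0.06 under quantile normalization against 0.75. No biological explanation was tested. Probes higher in girdle than fetus showed no such rise (median -0.24, 12.3% up at least 2-fold, against -0.29 and 15.1% for lower probes). This cannot decide whether girdle shares a programme with stimulated lymphocytes, because one that fetus also carries would cancel in that comparison. The pattern rests on 1 array per lymphocyte condition, and genes are not independent.

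The girdle minus chorion differences of conceptuses 3637 (day 33) and 3961 (day 35) correlated least across probes, at r = 0.708, against 0.785 to 0.880 for the other 5 conceptus pairs. Removing the GC trend left a gap of 0.068 ± 0.007 (bootstrap SD) to the lowest other r, against 0.077 before, which argues against GC content as the whole cause. Independent noise in each conceptus's arrays would give at least 0.75 from the other correlations, and r fell short of that by 0.039 ± 0.004. The bootstrap SDs here are over probes and hold no spread between conceptuses, so this shortfall does not settle whether array noise accounts for the low r. Dim spots stay open, since the gap was 0.055 ± 0.006 among the 3537 probes with the highest mean level, within its spread of the bound of 0.05 set for it. Day of gestation may also contribute, with r = 0.880 for the pair on the same day, 0.785 to 0.844 for pairs 1 day apart and 0.708 for the only pair 2 days apart, but it cannot be told apart from the individual conceptuses and slides.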
